A study of Mus musculus with 6 samples.

How the data were processed

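RNA from 3 samples of male gonadal somatic cells from the fetal gonad (soma) and 3 samples of the embryonic stem cell line VR15 (ESC) was measured on Agilent mouse arrays with 1 dye. Per the labels' protocols, total RNA was labelled with Cy3 by a low input kit with spike-in RNA added, and each sample had its own array. Per the file headers, Feature Extraction 10.7.3.1 read the scans and the processed signal is an intensity that was background-subtracted and detrended within the array, with no scaling between arrays. The deposited series matrix holds log2 values with no stated scale. Its values are those of the processed signal on the log2 scale, less the array's 75th percentile and less each probe's median over the 6 arrays: at least 99.97% of 39429 probes lay within 0.01 of that calculation, and the correlation per array across probes was 0.9997 or more. The medians of its columns were 0.055, -0.25 and -0.0654 for soma 1 to 3 and 0.161, -0.0879 and 0.0634 for ESC 1 to 3. Since each probe is centred over both groups, the matrix served as an alternative and the scanner values as the source.

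The log2 processed signal of each gene spot was scaled by subtracting the array's 75th percentile. Spots of 1 probe were averaged, spots with an outlier mark were left out (15 probe values), and 1377 control spots were left out. A probe was kept when it was well above background, by the scanner software's mark, on all arrays of at least 1 group, which held for 24153 of 39429 gene probes. Gene symbols came from matching the probes' transcript identifiers to a gene table of the GRCm38.p6 assembly, which gave a symbol to 66.1% of gene probes. No coordinates were used, and the array's own grid was built on an earlier assembly. A gene was represented by its brightest kept probe over all 6 arrays, and a probe with no symbol was kept under its identifier, for 14206 genes with a symbol and 5467 without. Of 3805 genes with several kept probes, 370 (9.72%) had probes that passed in opposite directions, 43 of them with 2-fold changes both ways. A gene not well above background on any array of 1 group is given as a bound.

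The 2 groups were compared with limma 3.58.1 in R 4.3.3 (linear fit and empirical Bayes, two-sided), as ESC minus soma, with Benjamini-Hochberg adjustment over 19673 genes and a threshold of 0.05. Errors of differences are the SE of that fit. Gene lists fixed before the data were examined (35 lists, 15 of them on energy metabolism) were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, adjusted over the 35 lists. A list needed 5 tested members, and all 35 had them. After the data had been seen, each list's median was also set against 10000 random lists drawn from 20 bins of brightness, and the scan was tried as a random block. To follow patterns among replicates, 4 further lists (27 more germ cell genes, 20 primitive streak and early embryo genes, 20 interferon-stimulated genes and 21 more stress genes) were written before their values were looked at. Single values per array were compared with an exact permutation test, which cannot go below 0.1 with 3 arrays against 3.

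The genes named were chosen by a rule fixed before the data were examined. It takes the 6 largest differences in each direction among genes with a name, well above background on all arrays and with no overlap between groups. It adds the 2 largest differences in each direction from each energy list, the 3 members with the smallest adjusted p from each other list, and 21 genes fixed by name. It gave 136 genes, some of which are not reported here. Hk1, Mki67, Eomes, B2m, Phlda2, Snrpn, Foxl2 and Cdkn2c were named after their values were seen. So were the members named from the further stress list, which are Hspb1, Hsph1, Hspa8, Dnajb1, Ier5, Fosl2, Rhob, Egr2, Klf9, Socs3 and Gadd45b.

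Alternatives covered quantile normalization, scaling to the array median and to the spike-in probes, normexp background correction (offset 50), other filters on dim probes, the mean of a gene's probes, the series matrix, a variance trend with robust estimation, a test against a log2 difference of 1, the slide as a fixed or random block, the shared slide alone, the replicate number as a block, and each array left out in turn. Normexp was run on the spots' median signal, since the mean signal is not among the values used. The methods were tested on simulated data built on the 19673 genes of the comparison, with 200 genes changed. Of 50 genes changed by each log2 difference, 6% were recovered at 0.25, 32% at 0.5, 76% at 1 and 92% at 2, with 2 unchanged genes called. All 3 shifted lists passed, and 0 of 32 others did. In the data 85.0% of genes changed, far more than in the simulation, so the shares recovered do not carry over to the comparison. Simulated genes varied independently of each other, so the list result does not test camera where genes are correlated. No array was left out. The number of arrays limits the precision.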

Results

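Gene expression was measured on 6 one-colour arrays in 2 groups of mouse cells, with 1 array per sample. The soma group holds 3 samples of somatic cells from the fetal male gonad, taken from animals that carry a GFP reporter transgene. The ESC group holds 3 samples of VR15, a male embryonic stem cell line that carries a red fluorescent reporter of the germ cell gene Vasa. The labels call the 3 samples of each group biological replicates, and every p-value rests on that. The 75th percentile of the signal was 1337, 1388 and 1245 on soma 1 to 3 and 1016, 975.02 and 959 on ESC 1 to 3. The group means were 1323 ± 72.6 (SD, n = 3) and 983 ± 29.3 (SD, n = 3), with a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. Between 56.0% and 63.2% of gene probes were well above background on an array, and no spot was saturated. Pearson's r across the tested genes was 0.994 to 0.995 within groups and 0.786 to 0.7996 between them, where genes are not independent replicates. The number of arrays limits the precision.

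The study's title concerns the energy metabolism of primordial germ cells, and the arrays described here set embryonic stem cells against the somatic cells that surround germ cells in the gonad. The genes with the largest higher values in ESC were Trh, which encodes the precursor of thyrotropin-releasing hormone, at 747-fold (log2 difference 9.54 ± 0.21, SE, n = 3 per group), Zfp42, a stem cell marker also called Rex1, at 372-fold, Upp1, which encodes uridine phosphorylase, at 310-fold, the amino acid transporter gene Slc7a3 at 245-fold, Tdh, which encodes threonine dehydrogenase, at 203-fold, and the transcription factor gene Tfap2c at 189-fold. Another passing probe of Upp1 was also higher in ESC, but on each soma array it lay under the lowest signal among probes well above background, so no fold is given for it. The largest lower values in ESC were those of the alpha globin gene Hba-a2 at 2830-fold (log2 difference -11.47 ± 0.12, SE, n = 3 per group), the endothelin receptor gene Ednra at 509-fold, Sparcl1 at 400-fold, Clca3a1 at 394-fold, the renin gene Ren2 at 354-fold, and Cyp26b1, whose enzyme breaks down retinoic acid, at 306-fold. These 12 genes were the largest among named genes well above background on all 6 arrays, and their values did not overlap between the groups.

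Of 19673 genes tested with limma, 16712 (85.0%) changed at an adjusted p under 0.05, 9175 of them higher in ESC and 7537 higher in soma. At least 2-fold changes numbered 4766 higher in ESC and 4572 higher in soma. The balance moved with the scaling. Under spike-in scaling 7707 genes were higher in ESC and 8547 in soma, and under scaling to the array median 10232 and 6534. No soma array was well above background for 828 genes, of which 827 were higher in ESC, and no ESC array was for 1246 genes, of which 1239 were higher in soma. The filter fixed these directions, since such a gene had to be well above background on every array of the other group. The median difference of all genes was 0.14, and it moved by -0.12 under quantile normalization, by 0.196 under scaling to the array median and by -0.223 under scaling to the spike-in RNA. Soma 1 and 2 shared a slide and a scan, while soma 3 shared its slide with the 3 ESC arrays, which were scanned apart from it. No scan held both groups, so scan and group cannot be told apart. With the slide as a fixed block 15540 genes changed, and within the slide that holds both groups 15060 did. Both set the 3 ESC arrays against soma 3 alone (n = 1), so they give the same differences and are 1 check, and soma 3 is assumed to vary as the other arrays do.

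Pluripotency markers stood higher in ESC by a median log2 difference of 5.55. Of 24 genes tested, 22 rose, 1 fell and 1 did not pass. Pou5f1, the Oct4 gene, was 63.0-fold higher (log2 difference 5.98 ± 0.28, SE, n = 3 per group, adjusted p 5.01e-06). Sox2 rose by 7.19 (5.63 at its lowest under other scalings or normexp) and the growth factor gene Fgf4 by at least 792-fold. Klf5 and L1td1 were 63.9-fold and 95.5-fold higher. A bound such as that of Fgf4 is used for a gene not well above background on any array of 1 group. It sets the mean of the bright group against, on each dim array, the higher of the probe's own value and the lowest signal among probes well above background. Such a bound belongs to the main processing and is not a lower limit under the alternatives. Under other scalings or normexp the log2 differences fell short of it. At their smallest they were 8.20 for Fgf4, -7.14 for Cyp11a1, -3.02 for Nanos2 and -3.11 for Ppargc1a. Nanog was the member that fell, 2.84-fold (adjusted p 0.000153), on a single probe whose target could not be checked against sequence. The camera test put the list higher in ESC (adjusted p 1.55e-05; adjusted p = 0.396 with an estimated correlation). Against soma 3 alone, on the shared slide, its median was 5.19.

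Markers of the gonad's own somatic cells stood lower in ESC. Of 19 Sertoli genes, the supporting cells of the testis, 18 were higher in soma and 1 did not pass. Their median was -5.92, or -5.06 when 9 members are set at their bound and -4.38 under normexp background correction. Sox9, which drives testis determination, was at least 25.7-fold lower in ESC, Amh, the gene of anti-Müllerian hormone, at least 20.4-fold, and Defb19 at least 323-fold, and Nr5a1 fell by 7.19. Of 11 fetal Leydig genes, which serve androgen synthesis, 10 were higher in soma and 1 in ESC, with a median of -4.47 (-3.84 with bounds, -2.88 under normexp background correction). Cyp11a1, whose enzyme makes pregnenolone from cholesterol, was at least 391-fold lower in ESC, Star fell by 6.28 and Cyp17a1 by 2.90. All 18 interstitial and stromal genes were higher in soma (median -5.61, or -5.52 with bounds and -4.82 under normexp). Among them were Maf, by at least 106.7-fold, and Nr2f2, which fell by 8.98 (-7.30 at its smallest under other scalings or normexp). The camera adjusted p was 3.17e-07 for the Sertoli list, 0.000156 for the Leydig list and 3.17e-07 for the stromal list (adjusted p = 0.198 with an estimated correlation for each of the 3).

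Markers of blood and vessels were also measured in soma. All 9 erythroid genes were higher in soma, with a median of -11.47 (-10.20 with bounds, -8.88 under normexp). They include the embryonic globin genes Hbb-y, by at least 10450-fold, and Hba-x, by at least 1179-fold. Under other scalings or normexp Hbb-y and Hba-x stood at -12.04 and -8.88 at their smallest. Of 12 macrophage and leukocyte genes 11 were higher in soma and 1 in ESC (median -3.44, or -3.14 with bounds and -2.05 under normexp), with Cx3cr1 lower in ESC by at least 54.9-fold and C1qc by at least 23.1-fold. The camera adjusted p was 5.7e-05 for the erythroid list and 0.00105 for the leukocyte list, and each had an adjusted p = 0.198 with an estimated correlation. The leukocyte list no longer passed when only its 5 members well above background on all arrays were tested (median -2.40, adjusted p 0.103). Endothelial genes were mixed, with 7 of 12 higher in soma, 2 higher in ESC and 3 that did not pass. Cdh5, the gene of the junction protein VE-cadherin, was at least 36.9-fold lower in ESC and Emcn at least 11.2-fold, and the list as a whole missed the threshold (median -1.86, or -1.45 with bounds, -1.03 under normexp and 0.20 over the 7 members well above background on all arrays, camera adjusted p 0.0512). Both other tissue lists also missed it. Of 6 mesonephric genes 4 were higher in ESC and 2 in soma. Krt8 rose by 2.75, Lhx1 by 1.67 (0.85 at its lowest under other scalings or normexp) and Emx2 was at least 26.5-fold lower in ESC. The median of the mesonephric list was 1.35 (0.69 under normexp) and its mean 0.04 (camera adjusted p 0.826). Camera put that list higher in ESC while fry put it lower. Of 8 ovarian somatic genes 3 were higher in ESC and 4 in soma (median -1.13, or -0.65 under normexp, camera adjusted p 0.502). Fst rose by 5.37, Irx3 rose by 1.89 (0.97 at its lowest under other scalings or normexp) and Rspo1 fell by 2.19. The other member higher in ESC, Foxl2, stood at 0.21 on a probe with a high signal on all 6 arrays, whose target could not be checked against sequence, while its other probe was not well above background on any array.

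Germ cell markers were split. Of 15 genes 9 were higher in ESC, 2 were higher in soma and 4 did not pass (median 1.06, or 0.53 against soma 3 alone, camera adjusted p 0.298). Sycp3, a gene of the meiotic chromosome axis, rose by 5.40 and Prdm1, a regulator of germ cell fate, by 2.75. Nanos2, a gene of male germ cells, was at least 16.2-fold lower in ESC and Dazl fell by 2.06. Ddx4, the Vasa gene, differed by 0.13 ± 0.28 (SE, n = 3 per group, adjusted p 0.671). Against soma 3 alone (n = 1), the soma array with the highest Ddx4, it differed by -0.40. The germ cell list differed among the soma arrays, with median deviations from the soma mean of -0.56, 0.06 and 0.48 on soma 1 to 3. Pluripotency markers deviated there by -0.28, 0.06 and 0.24, while Sertoli markers (0.16, 0.00 and -0.14) and endothelial markers (0.20, -0.05 and -0.14) were highest on soma 1. Matrix genes deviated by -0.05, -0.06 and 0.11. The Y-linked genes Ddx3y and Eif2s3y differed by 0.04 (adjusted p 0.515) and 0.89 (adjusted p 0.000107), where Ddx3y stood at 0.24 under scaling to the array median, which passed, and below 0 under spike-in scaling (-0.18) and quantile normalization, which did not. Xist was not well above background on any array.

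Genes of glycolysis, the route from glucose to pyruvate and lactate, stood higher in ESC. Of 20 genes tested 18 were higher in ESC, 15 of them by at least 2-fold, 1 was lower and 1 did not pass. The median was 1.98, or 1.37 under quantile normalization, where 17 were higher and 3 lower. Pfkp, the platelet form of phosphofructokinase, was 42.9-fold higher (log2 difference 5.42 ± 0.06, SE, n = 3 per group, adjusted p 1.47e-07), although another of its probes gave 1.03. Hexokinase 2, from Hk2, was 9.47-fold higher (3.24 ± 0.07, SE, n = 3 per group). Pkm, which encodes pyruvate kinase, rose by 2.41 and the lactate dehydrogenase gene Ldha by 2.05. Other probes of Ldha gave 3.18 and 3.28. Ldhb rose by 0.31 but stood at -0.36 under quantile normalization. The muscle form Pfkm fell by 0.49, and Hk1 differed by 0.03 (adjusted p 0.648). The camera adjusted p for the list was 0.000148 (adjusted p = 0.266 with an estimated correlation). Against soma 3 alone, on the shared slide, its median was 1.94. Random lists matched on brightness had medians of 0.127 to 0.81 (central 95% of 10000 lists), and the glycolysis list lay above 100% of them.

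Genes that bring glucose, lactate and pyruvate into the cell and the mitochondrion went both ways. The glucose transporter gene Slc2a3 was 64.0-fold higher in ESC, with an SE of 0.10 on the log2 scale, and Slc2a1 was 11.1-fold higher (log2 difference 3.47 ± 0.05, SE, n = 3 per group). Slc2a4, the gene of the insulin-responsive glucose transporter, fell by 2.83. Pdk1, a kinase that restrains pyruvate dehydrogenase, rose by 2.68, and its relative Pdk2 fell by 1.83. Of the 20 genes of this list 9 were higher in ESC, 7 were higher in soma and 4 did not pass (median 0.12, camera adjusted p 0.832), and the median was -0.06 under quantile normalization, -0.11 under spike-in scaling and -0.03 without soma 2.

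Respiratory genes stood slightly higher in ESC, by amounts that moved with the scaling. Of 36 complex I genes 31 were higher in ESC, 1 was lower and 4 did not pass (median 0.56). Ndufs6 rose by 1.37 and Ndufa7 by 1.36, and Ndufa3 fell by 0.23 but stood at -0.03 under scaling to the array median, where it did not pass. Of 25 genes of complexes III and IV 22 were higher and 1 was lower (median 0.91), with Cox6a2 at 2.83, Cox5a at 1.76 and Cox4i2 at -1.09. Of 15 ATP synthase genes 14 were higher and none lower (median 0.59), with Atp5l at 0.94 and Atp5b at 0.92, but under quantile normalization the median was -0.04, with 4 higher and 6 lower. In the tricarboxylic acid cycle 14 of 17 genes were higher and 1 was lower (median 0.45), with Idh3a at 1.86 and Suclg1 at 0.94, while Idh2, which encodes the NADP-dependent mitochondrial isocitrate dehydrogenase, fell by 2.30 ± 0.05 (SE, n = 3 per group). The camera adjusted p was 0.000156 for complex I, 0.000554 for complexes III and IV and 0.0394 for the cycle (adjusted p = 0.43 with an estimated correlation for each), and 0.0056 for ATP synthase (adjusted p = 0.473 with an estimated correlation). Under quantile normalization the medians of complex I, complexes III and IV and the cycle were 0.09, 0.21 and 0.04, with 15 higher and 11 lower, 16 and 5, and 5 and 6, and none of the 4 lists passed. Relative to the median of all genes, complex I, complexes III and IV, ATP synthase and the cycle stood at 0.41, 0.76, 0.44 and 0.31, and under quantile normalization at 0.07, 0.18, -0.06 and 0.01. Bright genes sat higher in ESC in general, so that against lists matched on brightness complex I lay above 46.9% of them, ATP synthase above 49.7%, the cycle above 30.9% and complexes III and IV above 99.0%. Against soma 3 alone the medians of complex I, ATP synthase, the cycle and complexes III and IV were 0.56, 0.54, 0.48 and 0.84, and the cycle had an adjusted p of 0.0592.

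Genes of amino acid and one-carbon metabolism rose together in ESC. All 13 genes of glutamine and amino acid entry were higher in ESC, 10 by at least 2-fold (median 1.96). The glutaminase gene Gls2 rose by 4.55 ± 0.06 and the asparagine synthetase gene Asns by 4.36 ± 0.07 (SE, n = 3 per group). Of 17 genes that feed folate and methyl groups from serine and threonine, 16 were higher and 1 was lower (median 2.77). Tdh rose by 7.67 ± 0.11 and Gldc of the glycine cleavage system by 5.51 ± 0.17 (SE, n = 3 per group). The camera adjusted p was 0.000139 for the glutamine list (adjusted p = 0.198 with an estimated correlation) and 8.33e-05 for the one-carbon list (adjusted p = 0.266 with an estimated correlation). Against soma 3 alone the medians were 1.90 and 2.76. Both lists lay above 100% of the random lists matched on brightness.

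Genes of fatty acid breakdown and lipid synthesis went both ways. Of 20 genes of mitochondrial fatty acid oxidation 13 were higher in soma, 6 were higher in ESC and 1 did not pass (median -0.52). Acaa2, which encodes the thiolase of the last step, fell by 3.89 ± 0.07 (SE, n = 3 per group) and Eci2 by 1.53, while Acadm and Cpt1c each rose by 1.45. The list had a camera adjusted p of 0.0639 and lay above 0.6% of the lists matched on brightness, and under quantile normalization its median was -0.81 (adjusted p 0.0296) and under scaling to the array median -0.32. Fatty acid synthesis had 7 genes higher in soma and 5 in ESC (median -0.49, or -0.30 under scaling to the array median, camera adjusted p 0.428), where Me1, the gene of malic enzyme, fell by 3.31, Acss2 fell by 1.12, and Scd1 and Acacb rose by 2.26 and 1.86. Sterol synthesis had 9 genes higher in soma, 8 in ESC and 3 that did not pass (median -0.13, camera adjusted p 0.493), and the median was 0.06 under scaling to the array median and -0.40 under quantile normalization. Its members ranged from Tm7sf2, which fell by 1.65, and Hsd17b7, which fell by 1.39, to Ebp at 0.85.

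The remaining energy lists leaned towards ESC without passing camera. Of 9 pentose phosphate genes 8 were higher in ESC and 1 was lower (median 0.998, or 0.56 under quantile normalization, camera adjusted p 0.0512), with Prps1 at 3.05, Prps2 at 1.68 and Rpia at -1.36. Among 19 antioxidant genes 14 were higher in ESC and 5 in soma (median 0.9989, or 0.48 under quantile normalization, camera adjusted p 0.0512). Sod2, the mitochondrial superoxide dismutase gene, rose by 2.83 and Gclm by 2.48, while Gpx3 fell by 1.75 and Prdx3 by 0.62. The hypoxia list had 9 genes higher in ESC, 3 higher in soma and 2 that did not pass (median 0.80, camera adjusted p 0.131), where Bnip3, a gene of mitochondrial clearance, rose by 3.57 and Egln3 by 2.95, and Vegfa and P4ha1 fell by 1.28 and 1.38. Other probes gave -0.27 for Vegfa and -0.29 for P4ha1. Mitochondrial biogenesis and dynamics had 12 genes higher in ESC, 4 lower and 1 that did not pass (median 0.52, or 0.30 under spike-in scaling, camera adjusted p 0.11). Ppargc1a, a coactivator that promotes mitochondrial biogenesis, was at least 18.8-fold lower in ESC, Mfn2 fell by 0.67, and the polymerase gene Polg rose by 1.42. Ssbp1 stood at 1.51 on its brightest probe, at -1.05 and -0.25 on its others, and at 0.07 for their mean, which did not pass. Fis1 stood at -0.32 on its brightest probe and at 1.30 on its other. Actb, a common control gene, rose by 0.28 (adjusted p 0.0186) but stood at -0.15 under quantile normalization.

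**Figure D1:**
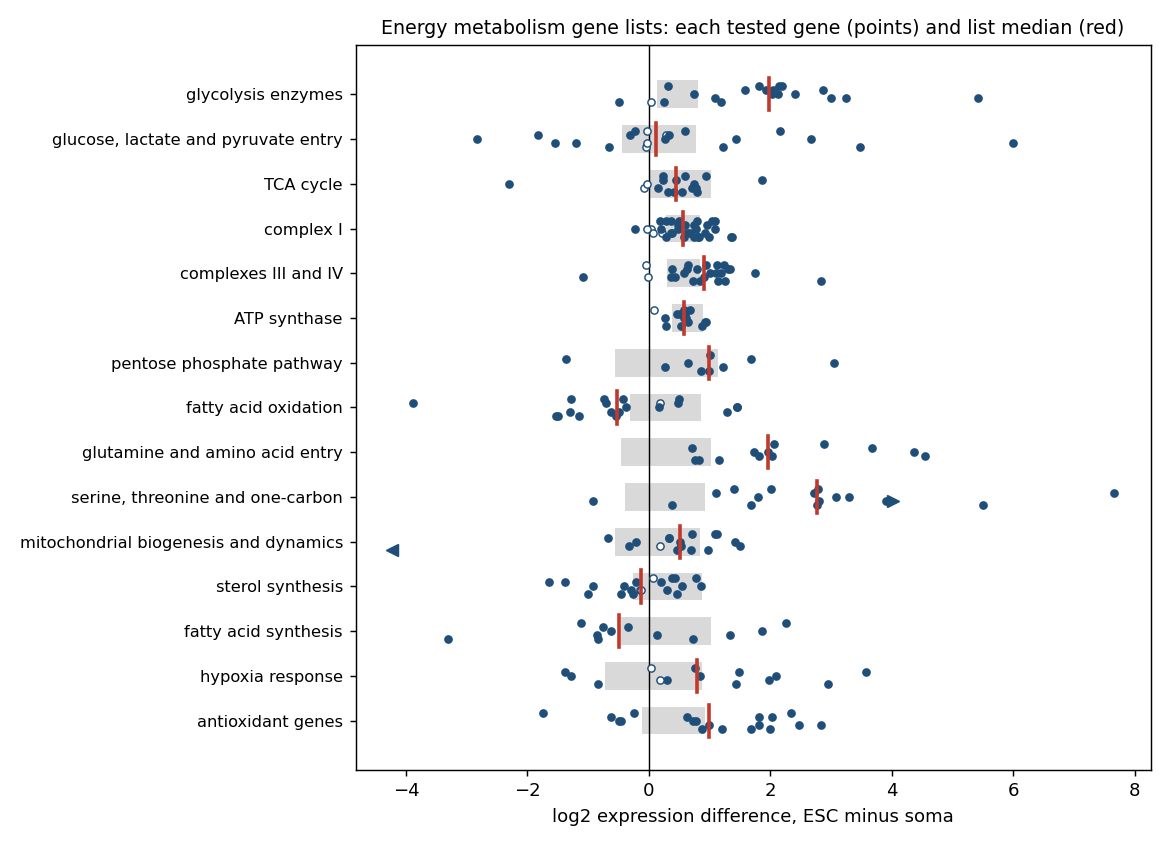
Differences between ESC and soma (log2, ESC minus soma) of the tested genes of the 15 energy lists, filled where the adjusted p is under 0.05 and open otherwise, with triangles for bounds, a red bar at each list's median and a grey band for the central 95% of medians of 10000 random lists matched on brightness. The medians of the one-carbon, glycolysis and glutamine lists (2.77, 1.98 and 1.96) lie above their bands, and those of complex I and ATP synthase (0.56 and 0.59, the latter -0.04 under quantile normalization) lie inside theirs.

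Adjusted over the list alone, the numbers of genes higher in ESC and in soma were those given over all genes for 33 of the 35 lists. Adjusted over the list alone, mitochondrial biogenesis and dynamics had 13 genes higher in ESC in place of 12, and imprinted genes had 16 higher in soma in place of 15. Camera passed 19 of the 35 lists, 11 higher in ESC and 8 higher in soma, and none passed with an estimated correlation, where the smallest adjusted p was 0.198. By fry, which asks whether a list moves on balance one way and does not set it against other genes, 34 lists passed.

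**Figure D2:**
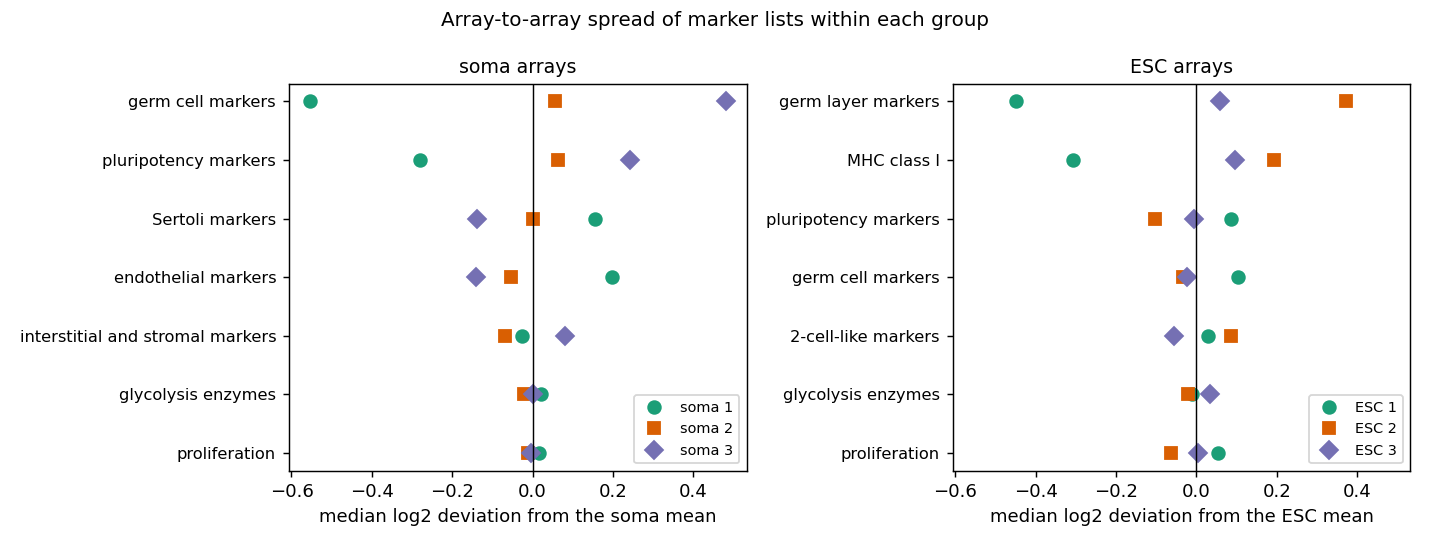
Median deviation of each list's genes from the mean of their group (log2) on each array, for 7 lists in the 3 soma arrays and 7 lists in the 3 ESC arrays. Germ cell markers span 1.04 among the soma arrays and germ layer markers 0.82 among the ESC arrays, while the glycolysis list spans 0.04 and 0.05.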

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

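The scan as a random block was the only alternative chosen after the result was seen. Of 2804 comparisons of a named gene under an alternative, 2764 kept their direction and their side of the threshold, as did 705 of 799 comparisons of a list. Most named genes were chosen for large differences or small adjusted p in these data, which favours such stability. For camera with an estimated correlation only the side of the threshold was compared. The number of changed genes was 16464 under quantile normalization, 16766 under median scaling, 16254 under spike-in scaling, 16591 under normexp, 16708 from the series matrix and 16055 to 16589 with 1 array left out. It was 16633 with the slide and 16801 with the scan as a random block, and every list kept its direction and side under both. No scan held both groups, so the scan block could not take a scan effect out of the group difference. Its estimated correlation was -0.0329. With the slide as a fixed block every list did so too, but that fit, like the shared slide alone, sets the ESC arrays against soma 3 only. The replicate numbers do not pair the arrays: the correlations across genes of the deviations of same-numbered soma and ESC arrays were -0.0473, 0.0672 and 0.0274. With a replicate block, 16479 genes changed and the tricarboxylic acid cycle had a median of 0.45 and an adjusted p of 0.0506. Against a log2 difference of 1, which asks for more by its construction, 7595 genes changed, 3854 higher in ESC and 3741 higher in soma, and this setting gives no list test. The alternatives without saturated probes and without a far array were not run, since no spot was saturated and no array stood apart. What lies near background limits the dim genes: with the filter for all 6 arrays, 2815 genes were higher in soma by 2-fold out of 16088 tested, by construction fewer than with the main filter.

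Single genes that reversed and passed were Ldhb (-0.36) and Actb (-0.15) under quantile normalization and Fis1 (0.49) with the mean of its probes, which point both ways. Ddx4 changed sign (-0.40) within the shared slide and with the slide as a fixed block. Soma 3 stands alone in both (n = 1), so they settle no call for Ddx4. Ddx4 (-0.0898) and Ddx3y (-0.18) also changed sign under spike-in scaling and Ddx3y (-0.0020) under quantile normalization, without passing. With 1 array left out, Ddx4 ranged from -0.17 (without soma 1) to 0.40 and Ddx3y from -0.000105 (without ESC 1) to 0.0647. The mean of a gene's probes also ended the call of Ssbp1 (0.07). Median scaling ended those of Ndufa3 (-0.03) and Fis1 (-0.13), and spike-in scaling those of Ldhb (0.09) and Actb (0.06), while median scaling gave Ddx3y (0.24) a call. The slide as a fixed block and the shared slide alone ended the call of Actb (0.12 in both), and testing without a filter ended that of Ndufa3 (-0.23). The test against a log2 difference of 1 ended 16 calls of named genes. Leaving out soma 1, soma 2, ESC 1 or ESC 2 ended the call of Actb (0.22 to 0.36 with 1 array left out), and leaving out ESC 2 ended that of Ndufa3 (-0.20).

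Lists that no longer passed were the tricarboxylic acid cycle (0.0365), complex I (0.0892), complexes III and IV (0.21) and ATP synthase (-0.0398, reversed) under quantile normalization. The cycle also missed under spike-in scaling (0.23), normexp (0.42), the filter for all 6 arrays (0.45) and the shared slide (0.48). Macrophage and leukocyte markers (-2.40), DNA methylation and Polycomb (0.98) and Hox genes (-2.16) missed under that filter and again when only their members well above background on all arrays were tested, in both cases with fewer genes. Under both of these, endothelial markers (0.20) and germ layer markers (-0.20) changed sign without passing. Other lists that changed sign without passing were fuel entry under quantile normalization (-0.0605), spike-in scaling (-0.105) and with 1 array left out (-0.0323 without soma 2, up to 0.14), and sterol synthesis under median scaling (0.0628). Lists that now passed were fatty acid oxidation (-0.81) and germ layer markers (5.94) under quantile normalization, endothelial markers (-1.67) under median scaling, and, under spike-in scaling, the pentose phosphate pathway (0.78), antioxidant genes (0.78), endothelial markers (-2.08), germ layer markers (5.80) and MHC class I (1.14). Without a filter these were the pentose phosphate pathway (0.998), fatty acid oxidation (-0.52), mitochondrial biogenesis and dynamics (0.52), antioxidant genes (0.9989), endothelial markers (-1.86), germ layer markers (5.31), dissociation stress (-0.79) and MHC class I (1.51). Fatty acid oxidation also passed with the filter for all 6 arrays (-0.52). With the mean of a gene's probes the pentose phosphate pathway (0.998), mitochondrial biogenesis and dynamics (0.53), antioxidant genes (1.21), endothelial markers (-2.49) and germ layer markers (5.69) passed. With a variance trend and robust estimation the pentose phosphate pathway (0.998), antioxidant genes (0.9989) and endothelial markers (-1.86) did. With 1 array left out, the median ranged from 0.43 to 0.46 for the cycle, which missed without soma 1 or ESC 3, from -1.92 to -1.77 for endothelial markers, which passed without soma 2, soma 3 or ESC 2, and from 0.94 to 1.01 for the pentose phosphate pathway, which passed without ESC 1 or ESC 2. It ranged from 0.98 to 1.02 for antioxidant genes, which passed without ESC 1, ESC 2 or ESC 3, from 5.80 to 6.09 for germ layer markers and from 1.31 to 1.46 for MHC class I, both of which passed without ESC 1. Normexp gave smaller medians of -1.52 for Hox genes, 3.39 for germ layer markers and 2.83 for 2-cell-like markers, which kept their side of the threshold. Under quantile normalization the pentose phosphate pathway and antioxidant genes had smaller medians of 0.56 and 0.48. Apart from those named with their construction, the cause was not tested.

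With an estimated correlation between genes, camera's adjusted p was 0.198 for the glutamine, Sertoli, Leydig, stromal, leukocyte, erythroid and Hox lists, 0.266 for glycolysis and one-carbon, 0.396 for the pluripotency, 2-cell-like, proliferation, DNA methylation, imprinted and matrix lists, 0.43 for the cycle, complex I and complexes III and IV, and 0.473 for ATP synthase. Fry, which by construction sets no list against other genes, gave lists that camera did not pass an adjusted p of 0.000198 (fuel entry), 1.32e-05 (pentose phosphate), 6.28e-05 (fatty acid oxidation), 0.000121 (mitochondrial biogenesis), 0.000547 (fatty acid synthesis), 1.04e-05 (hypoxia), 1.62e-06 (antioxidant), 0.00763 (germ cell), 3.54e-05 (endothelial), 0.0206 (ovarian), 1.52e-05 (germ layer), 1.32e-05 (dissociation stress) and 0.000177 (MHC class I). It gave 0.000225 for mesonephric markers and 2.26e-05 for CDK inhibitors, both in the direction opposite to camera's.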

Other observations

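The comparison of soma 1 with soma 2 for germ cell genes and the comparison with random lists matched on brightness were chosen after the result was seen. Genes of DNA replication and mitosis stood higher in ESC, with 21 of 22 higher and Mki67 lower (-0.35). Ccne1, the gene of cyclin E, rose by 3.67 ± 0.08 (SE, n = 3 per group), Bub1 by 1.80 and Cdc20 by 1.78, and the list had a median of 1.23 (camera adjusted p 8.33e-05; adjusted p = 0.396 with an estimated correlation). CDK inhibitors split into 3 higher and 4 lower, where Cdkn1a rose by 4.43, Cdkn2b was at least 11.9-fold higher, and Cdkn2c and Cdkn1c fell by 2.88 and 2.23. Their median was -0.20 (-0.39 under quantile normalization and -0.01 under median scaling) and their mean 0.91 (camera adjusted p 0.902), and camera put the list lower in ESC while fry put it higher. Genes of DNA methylation and Polycomb were higher in ESC in 13 of 15 cases (median 1.23, or 0.80 under quantile normalization, camera adjusted p 0.0195; adjusted p = 0.396 with an estimated correlation). Tested on its 13 members well above background on all arrays, this list no longer passed (median 0.98, adjusted p 0.057). Among the methyltransferase genes Dnmt3b rose by 4.59 and Dnmt3l by 9.45 (8.23 at its lowest under other scalings or normexp), while Dnmt3a fell by 3.27. Markers of the 2-cell-like state had 6 of 7 higher in ESC (median 5.85, or 3.83 with 3 bounds and 2.83 under normexp, camera adjusted p 0.0296; adjusted p = 0.396 with an estimated correlation), with Zscan4f at least 555.8-fold higher, Tcstv3 at least 16.5-fold and Tcstv1 at least 14.3-fold. Germ layer markers had 8 of 11 higher in ESC and 1 lower (median 6.02, or 4.91 with bounds, 3.39 under normexp and -0.20 over the 5 members well above background on all arrays, camera adjusted p 0.0577), with Foxa2 at least 42.4-fold and Zic2 at least 24.8-fold higher and Pou3f1 up by 3.59. Of 9 MHC class I genes 8 were higher in ESC, with Psmb8 at 4.28, Psmb9 at 3.43 and H2-D1 at 1.33, while B2m fell by 0.72 (median 1.36, camera adjusted p 0.0577).

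Genes of body position, matrix and imprinting stood higher in soma. Of 25 Hox genes 23 were higher in soma, 1 did not pass and 1 was higher in ESC (median -3.56, or -2.76 with 14 members at their bound and -1.52 under normexp). Hoxc6 fell by 6.84 ± 0.06 (SE, n = 3 per group), and Hoxd9 and Hoxd3 were at least 115-fold and at least 21.5-fold lower in ESC. The Hox list had a camera adjusted p of 1.12e-06 (adjusted p = 0.198 with an estimated correlation), and it no longer passed on its 5 members well above background on all arrays (median -2.16, adjusted p 0.127). Matrix genes were higher in soma in 17 of 21 cases and higher in ESC in 3 (median -3.55, camera adjusted p 5.7e-05; adjusted p = 0.396 with an estimated correlation), with Col5a2 at least 100.0-fold lower in ESC, Col4a2 lower by a log2 difference of -5.79 and Mmp2 by one of -4.69. Imprinted genes were higher in soma in 15 of 21 cases and higher in ESC in 5 (median -1.81, camera adjusted p 0.0108; adjusted p = 0.396 with an estimated correlation). Dlk1 fell by 5.89 and Mest by 3.74, while Ascl2 rose by 3.97, Snrpn rose by 2.88 and Phlda2 was at least 59.4-fold higher in ESC.

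Germ cell genes differed among the soma arrays, lowest on soma 1 and highest on soma 3. Their median deviation ranged by 1.04, where the 95th percentile of lists matched on brightness was 0.122. The p from those random lists was 1e-04, the smallest that 10000 lists can give, and no arrays were permuted. Ddx4 stood at -1.04, -0.38 and 0.08 on soma 1 to 3, Dazl at -1.23, -0.68 and -0.22, and Sycp3 at -3.43, -2.79 and -1.96, while the Sertoli (range 0.295) and endothelial (0.338) lists were highest on soma 1 and the matrix list (0.178) on soma 3, each beyond its matched lists. Against the slide or scan as the sole cause, soma 1 and 2 shared both and still differed by a median of 0.614 over 14 germ cell markers (central 95% of random lists -0.0659 to 0.104). Soma 3 had another slide and scan, so their part in its higher level cannot be told apart from the sample. A list of 27 further germ cell genes, 18 of them scored, had a range of 0.938 with soma 3 highest (95th percentile 0.113), so germ cells carried over in different amounts may account for the pattern. The labels name a GFP reporter and describe no sort or gate that would remove germ cells, several markers also occur in ESC, and no biological difference among the soma samples is given to test.

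Germ layer genes ranged by 0.821 and MHC class I genes by 0.501 among the ESC arrays, lowest on ESC 1 in both lists and highest on ESC 2, although the 3 arrays shared a slide and a scan. Eomes stood at -0.94, 0.09 and -0.25 on ESC 1 to 3 and Psmb8 at -0.62, 0.54 and 0.18, and pluripotency markers ranged the other way, highest on ESC 1 and lowest on ESC 2, by 0.19 (95th percentile 0.104). A list of 17 tested primitive streak and early embryo genes had a range of 0.84 (95th percentile of random lists 0.112), which is consistent with differentiating cells in different amounts. Of 20 interferon-stimulated genes, 16 of them scored, the range was 0.132 (95th percentile 0.105), so an interferon response in different amounts could add to the MHC class I pattern but at a far smaller size than 0.501. Both stay open as hypotheses, and no biological difference among the ESC samples is given to test.

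Immediate early and heat shock genes had 7 of 11 members higher in soma and 3 higher in ESC (median -0.79, camera adjusted p 0.118), with Hspa1a, Fosb and Fos down in ESC by log2 differences of -4.80, -4.73 and -3.34. A list of 20 tested further stress genes had 9 higher in ESC and 10 higher in soma, with a median of -0.253 against a lower 2.5% bound of -0.23 for lists matched on brightness. By that narrow margin handling stress of dissociated tissue stays possible, but the matched lists themselves centred on 0.361. The median of the first list lay inside its own matched band (-1.01 to 1.01). Of the heat shock genes in the further list, Hspb1 (2.84), Hsph1 (1.15) and Hspa8 (0.30) were higher in ESC and Dnajb1 (-0.68) in soma. Among its other members, Ier5 (-3.79), Fosl2 (-3.52), Rhob (-2.72) and Egr2 (-1.70) were higher in soma. Klf9 (4.58), Socs3 (1.37) and Gadd45b (1.13) were higher in ESC. Tissue against culture is also the difference between the groups, so a difference in cell type stays open and untested.

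Among replicates, 22 of 67 tests of a list within a group had a range above the 95th percentile of matched lists. Complex I among the ESC arrays was level with its 95th percentile (0.105) and was not counted. The tests reuse the same arrays, and the random lists hold genes that need not vary together. The 3.35 that independent tests would give is therefore not a fair measure of chance here. In the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many changed genes. With 10 splits a share under 0.05 cannot be reached. The real split gave 16712 genes with limma and the highest of the others gave 0 (16854 and 58 at an unadjusted p under 0.05). Every other split holds arrays of both groups on each side, so the group difference enters its error. Few calls could then be made, and the contrast is no measure of chance.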
